A study of Homo sapiens with 24 samples.

How the data were processed

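Total RNA from LNCaP cells was labelled with biotin and hybridised to Illumina expression arrays, per the labels' protocols. A deposited table held, for each of the 24 arrays, the raw probe intensity on a linear scale and a detection p-value per probe, per the file headers. A second deposited table held the authors' processed intensity values of the same arrays. GenomeStudio 2011.1 is named in the submitters' processing notes, and the role it had is not given in the sources used here. By their values, the processed columns were on a linear scale with medians of 116.356 to 116.393, shared a distribution within 1.28% at each rank and kept the order of the raw columns (Spearman correlation 1), which a quantile normalization without background subtraction gives. The method the authors used and whether other steps were taken stay unknown, and the processed table was used as an alternative. Samples were grouped by their titles. The compound's dose and the slides are not given in the sources used here.

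From the raw intensities and detection p-values, background correction by normexp, with the background estimated from the detection p-values, an offset of 16 and quantile normalization were run with neqc of limma 3.58.1 in R 4.3.3, with data.table version 1.17.8, and values were taken to log2. The offset draws the changes of dim genes toward 0. Probes with a detection p under 0.01 on at least 3 of the 24 arrays were kept, which left 17633 of 47323. Gene names came from the platform annotation, in which 30113 probes had 1 gene symbol, 8 had several and 17202 were not named. Symbols were checked by Entrez identifier against RefSeq genes of GRCh38, which updated 0 symbols and left 39 probes unmatched, and no coordinates were used. Of the probes kept, 4010 had no single gene name and stayed out of the gene tests. Where a gene had several kept probes, as 2633 did, the probe with the highest mean over the 24 arrays stood for it, which left 10345 genes, and other probes are given where they disagree. No arrays held the same values (0 pairs).

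A single limma fit of 8 group means over 24 arrays gave each contrast, with moderated statistics from eBayes and Benjamini-Hochberg adjustment within each contrast, and an adjusted p under 0.05 was called. Sharing the spread over all groups assumes that it is alike in them. The 4 treatment contrasts were ST045849 against vehicle and siOGT against scrambled at 12 and at 24 hours. Scrambled against vehicle, the differences between effects and between times, and each control's change over time were tested too. Where a gene's probe was not detected on any array of the dimmer group, the fold is a bound: the brighter group's mean of normalized log2 values against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes. Design, alternatives, gene lists and the rule for named genes were set beforehand. The rule named, per treatment contrast, the 10 largest rises and falls among called genes with the 3 treated arrays on 1 side of the 3 controls. For other contrasts it named 4 each way, and always OGT, OGA, MYC, KLK3, CDKN1A, DDIT3 and HSPA5, with 1 more gene not reported here, and the 4 members of smallest p as examples of each list.

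In all 27 gene lists were fixed from general pathway knowledge, and the 24 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 96 tests of 24 lists and 4 contrasts. Camera compares a list with the other genes, so that a shift common to all genes drops out. The lists were O-GlcNAc cycling, MYC targets, androgen response, G1/S, G2/M, ATF4, ER unfolded protein response, heat shock, NRF2, p53, cholesterol, fatty acid synthesis, glycolysis, glucose-responsive and hypoxia genes, respiratory chain, proteasome, ribosomal proteins, lysosome, interferon, NF-kB, aryl hydrocarbon receptor, metallothioneins, immediate early genes, apoptosis, and neuroendocrine, basal and stromal, and luminal markers. Some lists share members, and lists with strongly correlated genes are called too readily with the preset correlation, so the p with an estimated correlation is given beside each call. Lists in the other contrasts were adjusted in families of their own. Overlaps were tested with Fisher's exact test, and single transcripts also with exact permutation tests.

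Alternatives were no background correction, median scaling, the authors' processed values, other detection filters, all probes, the replicate number as a block, the compared groups alone, array quality weights, a fold threshold of 1.5, other set tests and leaving out each array. After the data were seen, vehicle as the control of siOGT, the mean siOGT effect over both times and 4 settings with array sets were added. The sets came from the largest gap of the vehicle arrays on the first principal component, by time and replicate number, and were carried to the other treatments. They entered as a block, as a block with its own effect of each treatment, as the time itself, and by keeping only the arrays whose set goes with their time. The labels name no batch. The 6 vehicle arrays analysed alone gave the same sets, while the same rule on the 6 arrays of each other treatment set 1 array apart. On the first component of a treatment's own 6 arrays the sets did not overlap in ST045849 and siOGT and did in scrambled, whereas on that of all 24 arrays they overlapped in no treatment. Counts between the sets that use vehicle arrays, also as the control of ST045849, are not independent of how the sets were found. On simulated data with 200 of 10345 genes changed, the limma fit called, for ST045849 against vehicle at 24 hours, 46% of genes set to a log2 change of 0.5, 96% at 1, 100% at -1 and 100% at 2, with 6.56% false calls. For siOGT against scrambled at 24 hours it called 36%, 98%, 94% and 100%, with 6.29% false calls. The simulation added independent normal noise to each gene's mean of normalized values, without array sets or correlated genes. It left out background correction, normalization, the detection filter and the choice of probe. It also changed a far smaller share of genes than the 24.3% called with ST045849 at 24 hours, so its rates need not hold for these data.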

Results

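The transcriptome of LNCaP cells, an androgen-sensitive line from a human prostate cancer metastasis, was measured on 24 one-colour Illumina bead arrays. O-GlcNAc transferase (OGT) is the enzyme that attaches N-acetylglucosamine to serine and threonine residues of nuclear and cytosolic proteins, and OGA is the enzyme that removes it. Cells received ST045849, a small-molecule OGT inhibitor, or its vehicle, and other cells received an siRNA against OGT (siOGT) or a scrambled siRNA, each for 12 or 24 hours. The 8 groups held 3 arrays each, which the submitters called biological replicates. The series concerns how this modification bears on the MYC protein, and each treatment was compared here with its own control at each time. The median raw intensity per array lay between 102 and 126, and 13993 to 16246 of the 47323 probes were detected, or 29.6% to 34.3%. Arrays of the same group correlated at 0.987 to 0.993 across the genes tested, and the number of arrays limits the precision of every value. On the first principal component, which held 34.2% of the variance, the 6 ST045849 arrays lay between 14.1 and 29.2, and the other 18 lay between -12.9 and -1.27. The vehicle arrays fell into 2 sets of 3 that crossed the labelled times, and this division was carried to the other treatments. The first set held 12 hours replicate 3 and 24 hours replicates 1 and 3, at 25.9 to 29.2 with ST045849 and -12.9 to -9.34 in the other treatments, and the second set lay at 14.1 to 20.4 and -6.34 to -1.27. The sets overlapped in no treatment on this component, but in scrambled the widest gap lay within the second set, from -6.34 to -2.62. Each comparison within a time is balanced over the sets, but the 24 hour groups hold 2 arrays of the first set and the 12 hour groups 1, so that every comparison between the times mixes time with set.

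The siRNA lowered its target. The OGT transcript stood at 7.19 ± 0.43 on the log2 scale with siOGT at 12 hours against 8.90 ± 0.12 with the scrambled siRNA (SD, n = 3), and 30.7% of the control level was left. The log2 change was -1.70 ± 0.23 (SE; limma adjusted p = 0.0040). At 24 hours OGT stood at 7.06 ± 0.67 against 8.89 ± 0.25, a log2 change of -1.83 ± 0.23 (adjusted p = 0.000679) that left 28.1%. A second OGT probe gave 36.1% and 30.5% left. The exact two-sided permutation test of 3 against 3 arrays gave p = 0.1 for either probe and time, the smallest it can give. With ST045849, OGT differed from vehicle by 0.48 ± 0.23 at 12 hours (adjusted p = 0.207) and 0.50 ± 0.23 at 24 hours (adjusted p = 0.122). These OGT changes passed the test with the array sets and their effect in each treatment in the model, a setting added after the data were seen (0.50, adjusted p = 0.00984, and 0.48, adjusted p = 0.0108), but not with the set as a block alone (adjusted p = 0.194 and 0.118). At 24 hours OGT also passed without background correction (adjusted p = 0.0247) and in a fit of the compared groups (adjusted p = 0.0174). OGA differed by 0.58 ± 0.30 (adjusted p = 0.236) and 0.68 ± 0.30 (adjusted p = 0.106) with ST045849, and by -0.78 ± 0.30 (adjusted p = 1) and -1.14 ± 0.30 (adjusted p = 0.139) with siOGT, and with the sets and their effect in each treatment in the model by 0.63 at each time (adjusted p = 0.000117 and 9.72e-05) and by -1.01 and -0.91 (adjusted p = 1.96e-05 and 5.25e-05). With the set as a block alone OGA passed in none of these (adjusted p = 0.157 and 0.0596 with ST045849, 0.945 and 0.0743 with siOGT). With the time taken from the set it passed with ST045849 at both times and with siOGT at 24 hours (-1.61), but not with siOGT at 12 hours (-0.31, adjusted p = 0.846). The MYC transcript differed by 0.11 ± 0.08 (adjusted p = 0.395) and 0.13 ± 0.08 (adjusted p = 0.256) with ST045849, where a second MYC probe gave -0.20 at 24 hours, and by 0.05 ± 0.08 (adjusted p = 1) and -0.03 ± 0.08 (adjusted p = 0.912) with siOGT. The OGT call with siOGT was lost when limma was fitted to the compared groups alone (adjusted p = 0.151 at 12 hours and 0.232 at 24 hours, the highest p of the settings without an array left out). It was also lost at 12 hours without siOGT replicate 3, where the change was -1.46 (adjusted p = 0.0595).

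**Figure D1:**
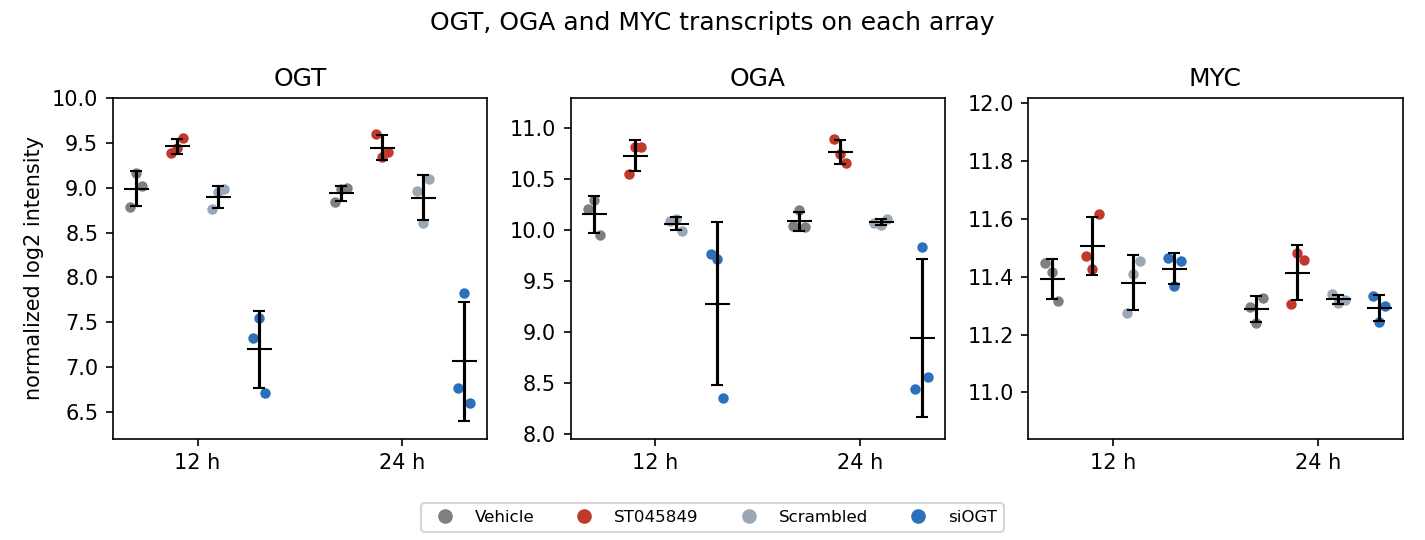
Normalized log2 intensity of the OGT, OGA and MYC probes on each array, by treatment and time; dots are arrays, horizontal marks are group means and bars are SDs over 3 arrays. OGT stood at 7.19 and 7.06 in the siOGT groups against 8.90 and 8.89 in the scrambled groups, and the MYC change passed the test in none of the 4 comparisons.

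ST045849 for 12 hours raised the genes of the ATF4 and amino acid response and lowered genes of DNA replication. DDIT3, the stress transcription factor CHOP, rose by 2.23 ± 0.19 on the log2 scale, or 4.70-fold (SE, n = 3 arrays per group; limma adjusted p = 2.62e-07). TRIB3, a pseudokinase induced by ATF4, rose 3.41-fold (1.77 ± 0.11, adjusted p = 3.75e-09). CDC25A, the phosphatase that activates cyclin-dependent kinases at the G1/S boundary, fell to 0.409 of its vehicle level (-1.29 ± 0.13, adjusted p = 2.6e-06). In all, 593 genes rose and 546 fell among the 10345 tested, and 431 of these changed by 1.5-fold or more. Other large rises were those of SLC7A5, the large neutral amino acid transporter (1.93 ± 0.15), SLC6A9, a glycine transporter (1.93 ± 0.17), and DDIT4, an inhibitor of mTORC1 signalling (1.89 ± 0.14). CHAC1, an enzyme of glutathione degradation, was not detected with vehicle and stood at least 2.41-fold higher with ST045849 (adjusted p = 3.88e-06). NIBAN1, a stress-induced gene, was at least 4.18-fold higher (adjusted p = 7.38e-06), and BCL11B, a zinc finger transcription factor, at least 1.77-fold higher (adjusted p = 1.1e-05), both also undetected with vehicle. AKR1C2 and AKR1C4, reductases of steroid metabolism, rose by 2.14 ± 0.31 and 1.87 ± 0.37, although the probes of these near-identical paralogs were not separated by sequence. Large falls were those of the replicative helicase genes MCM4 (-1.19 ± 0.15), MCM2 (-1.17 ± 0.16) and MCM10 (-1.17 ± 0.14), and of E2F2, a transcription factor of the S-phase programme (-1.16 ± 0.13). DDIAS (-1.28), DTL (-1.23), EXO1 (-1.16), UHRF1 (-1.16) and CDCA7 (-1.13) completed the 10 largest falls.

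Of the gene lists fixed before the data were examined, 24 had enough members for a test at 12 hours of ST045849, and 9 shifted by camera with a preset correlation. With an estimated correlation 3 of these calls held: the ATF4, G1/S and MYC target lists. Of the 36 ATF4 list members tested, 33 rose and none fell, and 36 rose when adjusted over the list alone (median log2 change 1.05, adjusted p = 6.74e-49; adjusted p = 0.00189 with an estimated correlation). STC2, a secreted glycoprotein, rose by 1.49 ± 0.11. Of 42 G1/S and DNA replication genes, 36 fell and none rose, with 39 falls adjusted over the list alone (median -0.78, adjusted p = 1.97e-35; adjusted p = 0.0248 with an estimated correlation). Of 51 MYC target genes, 20 fell and none rose, with 26 falls adjusted over the list alone (median -0.28, adjusted p = 7.19e-11; adjusted p = 0.00186 with an estimated correlation). Among them were PHB1, a mitochondrial scaffold protein (-0.37 ± 0.07), NOP16, a nucleolar ribosome biogenesis factor (-0.44 ± 0.09), and PA2G4, a growth-regulated RNA-binding protein (-0.40 ± 0.08).

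The other 6 calls at 12 hours were lost with an estimated correlation in the fit of 8 group means. With the array sets and their effect in each treatment in the model 7 lists were called with an estimated correlation at 12 hours: the 3 above, G2/M (adjusted p = 0.0109), NRF2 (adjusted p = 0.0109), heat shock (adjusted p = 0.0358) and ER unfolded protein (adjusted p = 0.0461). With the time taken from the set 4 were. Of 47 G2/M genes, 6 fell, or 13 adjusted over the list alone (median -0.54, adjusted p = 1.06e-10; adjusted p = 0.525 with an estimated correlation), among them MAD2L1 (-0.81 ± 0.17) and BIRC5 (-0.88 ± 0.20). The androgen response list shifted down, with 5 of 34 members lower and 3 higher, or 10 and 3 adjusted over the list alone (median -0.22, adjusted p = 0.0109; adjusted p = 0.586 with an estimated correlation). In it KLK3, which encodes prostate-specific antigen, fell by 0.76 (SE 0.18, adjusted p = 0.00898), and TMPRSS2, a serine protease, fell by 0.79 (SE 0.15, adjusted p = 0.00231). The NRF2 oxidative stress list shifted up, with 7 of 21 members higher, or 11 adjusted over the list alone (median 0.29, adjusted p = 8.91e-07; adjusted p = 0.292 with an estimated correlation). SLC7A11, the cystine transporter that the ATF4 list also holds, rose by 1.69 ± 0.23, and HMOX1, the heme-degrading enzyme, by 1.43 ± 0.34. The ER unfolded protein list had 7 of 31 members higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.16, adjusted p = 0.00285; adjusted p = 0.292 with an estimated correlation). XBP1, its transcription factor, rose by 0.70 ± 0.10 and the co-chaperone DNAJB9 by 0.80 ± 0.14, while HSPA5, the main ER chaperone, differed by 0.32 ± 0.13 (adjusted p = 0.117). HSPA5 was read by 1 probe, at a log2 level of 6.66 to 6.80 with vehicle at 12 hours, and the offset draws the changes of dim genes toward 0. HSPA5 passed with the array sets and their effect in each treatment in the model (0.37, adjusted p = 0.0398), but not with the time taken from the set (0.22, adjusted p = 0.216). Of 21 cholesterol genes 4 fell, or 5 adjusted over the list alone (median -0.31, adjusted p = 0.00323; adjusted p = 0.53 with an estimated correlation), among them INSIG1, a sterol sensor (-0.69 ± 0.19), and NSDHL, a synthesis enzyme (-0.51 ± 0.11). Of 26 lysosome and autophagy genes 4 rose, also adjusted over the list alone (median 0.09, adjusted p = 0.044; adjusted p = 0.417 with an estimated correlation), among them MAP1LC3B (0.60 ± 0.15). Median scaling in place of quantile normalization left 209 rises and 263 falls at 12 hours and ended the lysosome call (adjusted p = 0.0947), and a fit of the compared groups alone gave 452 genes. Without ST045849 replicate 3 the count was 486, and without vehicle replicate 3 it was 498.

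ST045849 for 24 hours raised 1406 genes and lowered 1110, and 971 of them changed by 1.5-fold or more. DDIT3 rose 6.19-fold (2.63 ± 0.19, limma adjusted p = 1.84e-08) and TRIB3 4.27-fold (2.09 ± 0.11, adjusted p = 1.47e-10; SE, n = 3 arrays per group). MCM10 fell by 1.61 on the log2 scale (SE 0.14, adjusted p = 1.08e-07), and RRM2, a subunit of the ribonucleotide reductase that makes deoxynucleotides, fell by 1.62 (SE 0.22, adjusted p = 3.1e-05). KLK3 fell to 0.50 of its vehicle level (log2 SE 0.18, adjusted p = 0.000439). NIBAN1 was at least 5.36-fold higher, CHAC1 at least 3.11-fold, and SERPINA3, a secreted protease inhibitor, at least 3.38-fold, each undetected with vehicle. AKR1C2 (2.42 ± 0.31), AKR1C4 (2.40 ± 0.37), SLC6A9 (2.11 ± 0.17), the calpain protease gene CAPN5 (2.09 ± 0.17) and the calcium-binding protein gene S100P (1.94 ± 0.34) were the other large rises. Large falls were those of DDIAS (-1.63 ± 0.21), the histone chaperone gene ASF1B (-1.61 ± 0.18), DTL (-1.61 ± 0.17), ATAD2 (-1.61 ± 0.23), the cytokinesis kinesin gene KIF23 (-1.57 ± 0.30) and CDC25A (-1.56 ± 0.13). EXO1 fell to 0.354 of its vehicle level and UHRF1 by 1.49, and a second UHRF1 probe gave -0.44. CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by 0.21 ± 0.21 (adjusted p = 0.491). With the time taken from the array set CDKN1A differed by 0.35 (adjusted p = 0.0063), and by -0.26 at 12 hours (adjusted p = 0.0829). With the array sets and their effect in each treatment in the model it differed by 0.12 at 24 hours (adjusted p = 0.442).

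At 24 hours 11 lists shifted with ST045849, and again 3 of these calls held with an estimated correlation. With the array sets and their effect in each treatment in the model 7 did, which added G2/M (adjusted p = 0.0109), NRF2 (adjusted p = 0.018), heat shock (adjusted p = 0.04) and ER unfolded protein (adjusted p = 0.0488), and with the time taken from the set 6 did. All 36 ATF4 list members rose, over all genes and adjusted over the list alone (median 1.19, adjusted p = 1.97e-35; adjusted p = 0.0053 with an estimated correlation). Of 42 G1/S genes 39 fell, or 40 adjusted over the list alone (median -1.04, adjusted p = 5.23e-35; adjusted p = 0.0248 with an estimated correlation). Of 51 MYC target genes 21 fell, or 27 adjusted over the list alone (median -0.26, adjusted p = 1.99e-08; adjusted p = 0.00279 with an estimated correlation), among them the nucleolar proteins NOP56 (-0.66 ± 0.10) and NCL (-0.58 ± 0.10). Of 47 G2/M genes 43 fell, or 46 adjusted over the list alone (median -0.95, adjusted p = 2.17e-20; adjusted p = 0.417 with an estimated correlation). CDK1, the mitotic kinase, fell by 1.46 (SE 0.23), and MAD2L1, of the spindle checkpoint, by 1.13 (SE 0.17). Of 34 androgen response genes 11 fell and 2 rose, or 13 and 2 adjusted over the list alone (median -0.28, adjusted p = 0.00287; adjusted p = 0.509 with an estimated correlation). TMPRSS2 fell by 0.90 (SE 0.15) and SGK1, a serum- and steroid-induced kinase, by 0.72 (SE 0.14). Of 21 NRF2 genes 14 rose, also adjusted over the list alone (median 0.59, adjusted p = 7.41e-06; adjusted p = 0.355 with an estimated correlation), among them AKR1C3 (1.83 ± 0.24) and the quinone reductase gene NQO1 (0.59 ± 0.12).

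Of 31 ER unfolded protein genes 12 rose at 24 hours of ST045849, or 13 adjusted over the list alone (median 0.19, adjusted p = 0.00127; adjusted p = 0.292 with an estimated correlation). DNAJB9 rose by 0.98 ± 0.14, and HSPA5 by 0.36 ± 0.13 (adjusted p = 0.0498), a call that median scaling ended (0.18, adjusted p = 0.434). The HSPA5 change was 0.21 without ST045849 replicate 1 (adjusted p = 0.276), and also 0.21 without background correction (adjusted p = 0.0556), and 0.46 with the time taken from the array set (adjusted p = 0.00195). It was 0.31 with the array sets and their effect in each treatment in the model, where the call ended (adjusted p = 0.0651). With the set as a block alone it was 0.36 (adjusted p = 0.0425). Of 22 cytosolic heat shock genes 8 fell and 1 rose, or 10 and 1 adjusted over the list alone (median -0.26, adjusted p = 0.00399; adjusted p = 0.417 with an estimated correlation), among them the HSP90 cofactor gene CHORDC1 (-0.64 ± 0.15). Of 21 cholesterol genes 6 fell and 1 rose, also adjusted over the list alone (median -0.40, adjusted p = 0.0072; adjusted p = 0.586 with an estimated correlation), among them the synthesis enzyme genes IDI1 (-0.93 ± 0.17) and EBP (-0.84 ± 0.18). Of 17 glucose-responsive and hypoxia genes 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (median 0.34, adjusted p = 0.044; adjusted p = 0.286 with an estimated correlation). TXNIP, an inhibitor of glucose uptake, rose by 1.03 ± 0.11, and VEGFA, an angiogenic factor that the ATF4 list also holds, by 1.70 ± 0.19. Of 26 lysosome and autophagy genes 6 rose, also adjusted over the list alone (median 0.17, adjusted p = 0.0306; adjusted p = 0.417 with an estimated correlation), among them MAP1LC3B (0.86 ± 0.15). Median scaling moved the median of all genes to -0.14, against 0.03 with quantile normalization, gave 362 rises and 1539 falls, turned the lysosome median to -0.03 and ended its call (adjusted p = 0.118). The ER unfolded protein median was 0.02 with median scaling, where its call held (adjusted p = 0.00977). Without background correction and with the authors' values the cholesterol median was -0.18 in both, with the call held (adjusted p = 0.00582 and 0.0058), and the glucose-responsive median 0.18 in both. The calls of the glucose-responsive and lysosome lists also ended among probes detected on all 24 arrays (adjusted p = 0.0806 and 0.0502).

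**Figure D2:**
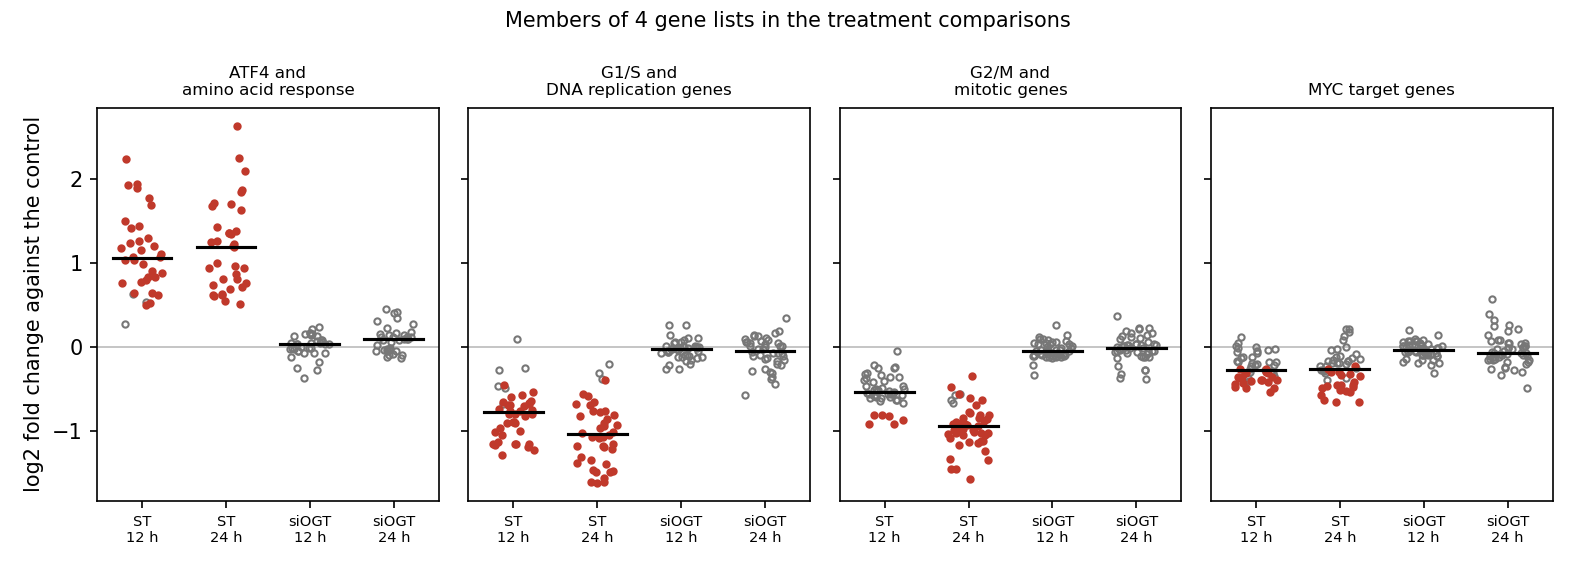
Log2 fold change against the control of each tested member of 4 gene lists with ST045849 (ST) and siOGT at 12 and 24 hours; filled red points have an adjusted p under 0.05, open points do not, and black lines are medians. The ATF4 median was 1.05 and 1.19 with ST045849 against 0.03 and 0.09 with siOGT, and the G1/S median was -0.78 and -1.04 against -0.03 and -0.05.

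The genes called with ST045849 at 12 and at 24 hours overlapped. Of the 593 genes that rose at 12 hours 479 also rose at 24 hours, where independent calls would share 80.6, and of the 546 that fell 418 also fell, where independent calls would share 58.6. The one-sided hypergeometric test gave -log10 p of 331 and 317, across genes that are not independent replicates. At 24 hours 586 of the 593 and 538 of the 546 had the same sign as at 12 hours, and the log2 changes correlated at 0.763 across all genes. No gene passed the limma test of the difference between the effects at the 2 times, with 669 genes at an unadjusted p under 0.05 where chance gives 517. This count of 0 rests on the labelled times: with the time taken from the array set it was 350, and with only the arrays whose set goes with their time 144. DDIT3 differed between the times by 0.40 ± 0.27 (adjusted p = 0.833) and KLK3 by -0.24 ± 0.25 (adjusted p = 0.883). The G1/S list had a median difference of -0.24 between 24 and 12 hours as labelled (adjusted p = 1.47e-06; adjusted p = 0.591 with an estimated correlation). The G2/M list had one of -0.43 (adjusted p = 7.25e-11; adjusted p = 0.591 with an estimated correlation). With a term for the array set and its effect in each treatment, added after the data were seen, these became -0.03 (adjusted p = 0.835) and -0.07 (adjusted p = 0.144), so the differences did not hold within the sets. If the sets are the true times, that term takes up the change over time, so this fit cannot speak against such a change.

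The ST045849 effect differed between the array sets more than between the labelled times. Between arrays of the same time and number, the G2/M median with ST045849 was -0.22, -0.22 and -1.16 for replicates 1, 2 and 3 at 12 hours, and -1.29, -0.17 and -1.33 at 24 hours. The G1/S median was -0.59, -0.61 and -1.26 at 12 hours, and -1.28, -0.59 and -1.27 at 24 hours. The ATF4 median was 0.95 to 1.03 on the 12 hour arrays of the second set and 0.89 on its 24 hour array, against 1.17 to 1.29 in the first set, and the MYC target median was -0.27 to -0.22 against -0.38 to -0.31. The group medians above are thus means over unlike arrays, while the direction was the same in both sets. The ST045849 effect differed between the sets for 240 genes, 59 higher and 181 lower in the first set (limma, 1407 at an unadjusted p under 0.05), a count that includes the vehicle arrays by which the sets were found. Without vehicle, the difference of the ST045849 arrays from scrambled differed between the sets for 200 genes (1200 unadjusted). The sets themselves differed for 175 genes in the ST045849 arrays (1224 unadjusted), 66 in siOGT (1263) and 34 in scrambled (1065). The siOGT effect differed for 3 (501 unadjusted). With siOGT against scrambled OGT changed by -2.50 to -2.20 in the first set and -1.44 to -0.79 in the second, and OGA by -1.64 to -1.55 and -0.39 to -0.22. With the set and its effect in each treatment in the model, ST045849 gave 1765 genes at 12 hours and 2276 at 24 hours and siOGT 6 and 8, while with the time taken from the set the counts were 950, 3377, 1 and 124.

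**Figure D3:**
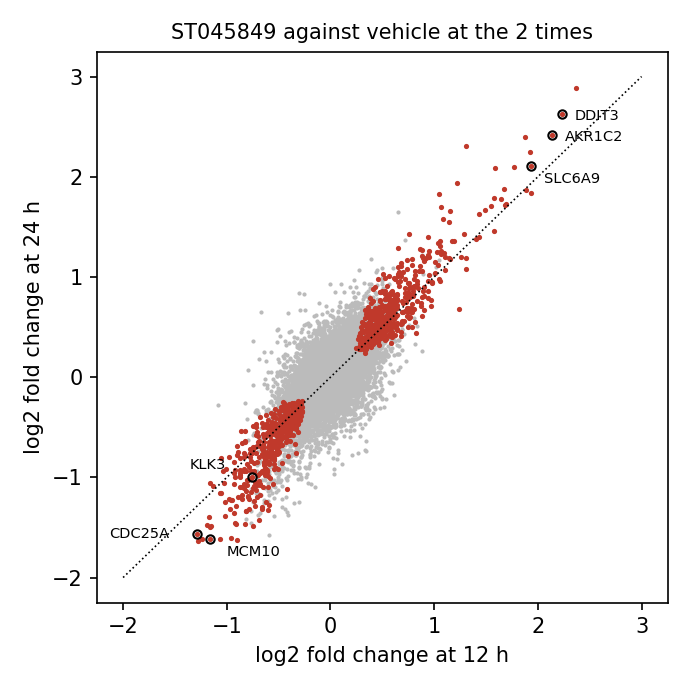
Log2 fold change of 10345 genes with ST045849 against vehicle at 24 hours over that at 12 hours, as fitted, including genes dim in vehicle whose fold the text gives as a bound. Red points passed the test at both times, the dotted line marks equal change, and circles mark named genes; the correlation across genes was 0.763.

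The scrambled siRNA was compared with vehicle as background to the knockdown. At 24 hours LMLN, a metallopeptidase gene, was not detected with the scrambled siRNA and was at least 1.41-fold higher with vehicle (limma adjusted p = 0.000588). FOXN4, a forkhead transcription factor gene, was at least 1.37-fold higher with the scrambled siRNA (adjusted p = 0.0163), and TEAD2, a transcription factor of Hippo signalling, rose by 0.65 ± 0.12 (adjusted p = 0.0475; SE, n = 3 arrays per group). In all 7 genes rose and 2 fell at 24 hours. At 12 hours limma called 0 genes, with 423 at an unadjusted p under 0.05. The cholesterol list was higher with the scrambled siRNA at 12 hours (median 0.15, adjusted p = 0.0262; adjusted p = 0.977 with an estimated correlation) and at 24 hours (median 0.23, adjusted p = 0.015; adjusted p = 0.977 with an estimated correlation), with 0 of 21 members called by limma at either time. The count at 24 hours was 1 without vehicle replicate 1 or 2, 2 without vehicle replicate 3 or scrambled replicate 1, and 45 without scrambled replicate 3. It was 2 with median scaling, neither of them a rise, and 0 in a fit of the compared groups.

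With siOGT for 12 hours OGT was the single gene called by limma, and 444 genes had an unadjusted p under 0.05 where chance gives 517. DDIT3 differed from scrambled by -0.01 ± 0.19 (adjusted p = 1) and KLK3 by 0.16 ± 0.18 (adjusted p = 1; SE, n = 3 arrays per group). Among the 24 lists the cholesterol genes alone shifted, upward by a median of 0.17 (adjusted p = 4.47e-05; adjusted p = 0.417 with an estimated correlation), with 0 of 21 members called over all genes or adjusted over the list alone. HMGCS1, which makes the precursor of mevalonate, differed by 0.41 ± 0.16 (adjusted p = 1). The ATF4 list had a median of 0.03 (adjusted p = 0.575), the G1/S list -0.03 (adjusted p = 0.384) and the MYC target list -0.05 (adjusted p = 0.118), with 0 members called in each, over all genes or adjusted over the list alone.

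With siOGT for 24 hours 3 genes rose and 10 fell, and 1323 genes had an unadjusted p under 0.05. Beside OGT, LMLN was at least 1.72-fold higher than with the scrambled siRNA, where it was not detected (limma adjusted p = 1.25e-05). IFT172, of intraflagellar transport, was at least 1.13-fold higher (adjusted p = 0.019), and LRRC1, a scaffold protein of cell polarity, rose by 0.55 ± 0.11 (adjusted p = 0.0408; SE, n = 3 arrays per group). The splicing factor gene YJU2 fell by 0.55 (SE 0.10, adjusted p = 0.0238), ZFR, an RNA-binding protein gene, by 0.51 (SE 0.09, adjusted p = 0.0334), UBXN2A by 0.48 (SE 0.08, adjusted p = 0.019), and RIPOR1 by 0.47 (SE 0.09, adjusted p = 0.0334). MIR1185-1 (-0.81), DPP7 (-0.51, with other probes at -0.18, 0.13 and 0.32) and MEIS3P1 (-0.42) also fell. ARFIP2 and CNNM4 were at least 1.26-fold and 1.28-fold lower than with the scrambled siRNA, undetected with siOGT. For ARFIP2 the difference lay in the scrambled arrays: at 24 hours scrambled minus vehicle was 0.85 and siOGT minus vehicle 0.0080. For CNNM4 these were 0.10 and -0.52. At 12 hours ARFIP2 differed from vehicle by -0.16 with scrambled and -0.30 with siOGT. DDIT3 differed by 0.18 ± 0.19 (adjusted p = 0.752), and 0 of the 24 lists shifted. With the time taken from the array set 124 genes were called in place of 13. With the array set as a block 3 lists shifted, with its own effect of each treatment 2 and with the time taken from the set 3, of which 0 held with an estimated correlation. The ATF4 median was 0.09 (adjusted p = 0.0528, the smallest of the 24 lists), with 0 of 36 members called over all genes and 1 adjusted over the list alone. The G1/S median was -0.05 (adjusted p = 0.146), with 0 of 42 called and 1 lower adjusted over the list alone, and the MYC target median was -0.07 (adjusted p = 0.203), with 0 of 51 called and 1 higher and 3 lower adjusted over the list alone. Median scaling left 1 rise and 1 fall, with the median of all genes at 0.11, and a fit of the compared groups left 0. The count was 2, 30 and 2 without siOGT replicates 1, 2 and 3, and 2, 3 and 25 without scrambled replicates 1, 2 and 3.

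The effects of ST045849 and siOGT were then set against each other through the difference of the 2 effects. At 12 hours 130 genes were higher and 77 lower in the ST045849 effect than in the siOGT effect, and at 24 hours 998 and 664. DDIT3 differed between the effects by 2.24 ± 0.27 at 12 hours (limma adjusted p = 7.03e-05), and DTL, which targets replication factors for degradation, by -1.34 ± 0.24 (adjusted p = 0.00442). PMS1, a mismatch repair gene, differed by -1.75 ± 0.32 at 24 hours (adjusted p = 0.00137). Of the 36 ATF4 list members 26 differed upward at 12 hours (median 0.97, adjusted p = 4.59e-48; adjusted p = 0.00416 with an estimated correlation) and 30 at 24 hours (median 1.09, adjusted p = 1.54e-26; adjusted p = 0.0273 with an estimated correlation). Of 42 G1/S genes 18 differed downward at 12 hours (median -0.75, adjusted p = 3.42e-31; adjusted p = 0.0454 with an estimated correlation) and 31 at 24 hours (median -0.92, adjusted p = 3.52e-25; adjusted p = 0.0856 with an estimated correlation). The MYC target list differed by -0.23 (adjusted p = 6.77e-07; adjusted p = 0.0119 with an estimated correlation) and by -0.21 (adjusted p = 0.000154; adjusted p = 0.0454 with an estimated correlation). The difference for the MYC transcript was 0.06 ± 0.11 (adjusted p = 0.838) and 0.16 ± 0.11 (adjusted p = 0.351).

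The calls of the treatments shared 1 gene, IFT172, higher at 24 hours, where independent calls would share 0.408 (Fisher's exact test, p = 0.355). MEIS3P1 was called in opposite directions at 24 hours (0.42 with ST045849, -0.42 with siOGT). At 24 hours 38.5% of the 1406 genes higher with ST045849 and 45.7% of those lower had the same sign with siOGT. At 12 hours 51.1% and 60.6% had it. The calls shared 0 of the genes lower at 24 hours, where independent calls would share 1.07 (Fisher's exact test, p = 0.614), and 0 in either direction at 12 hours. At 12 hours siOGT called OGT alone, and independent calls would share 0.0528 lower and 0 higher genes. With so few siOGT calls, these counts cannot show a lack of shared response. The log2 changes of the treatments correlated at 0.034 at 12 hours and -0.12 at 24 hours across genes, which are not independent replicates. No gene passed the limma test of the difference between the siOGT effects at 24 and 12 hours, with 375 at an unadjusted p under 0.05 (2 genes passed with the time taken from the array set), and the times shared the OGT call. Between 12 and 24 hours limma called 0 genes in vehicle, with 508 at an unadjusted p under 0.05, and 0 in scrambled, with 667. With the time taken from the array set these counts were 165 and 79, the first of them from the arrays by which the sets were found, so the labelled counts of 0 do not show that time had no effect. For the difference of the effects, median scaling left 41 higher and 16 lower at 12 hours, and 177 and 1393 at 24 hours with the median of all genes at -0.25, and a fit of the compared groups left 118 at 12 hours. The count at 12 hours was 98 without ST045849 replicate 3, 113 without vehicle replicate 3, 123 and 121 without scrambled replicates 1 and 2, and 133 without siOGT replicate 3, and that at 24 hours was 1062 without scrambled replicate 2.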

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

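The tests of the ATF4 and G1/S pattern, the LMLN test, the tests of the array sets and the 2 OGA tests that use sets were chosen only after the result was seen; the other tests that weigh a pattern below were written down earlier. The G1/S list differed between 24 and 12 hours of ST045849 by a median of -0.24 and the G2/M list by -0.43, and neither call held with an estimated correlation (adjusted p = 0.591 for each) or with the array sets in the model (-0.03 and -0.07). The set term would also take up a change over time if the sets are the true times. Among the 4010 detected probes without a single gene name, which the gene tests left out and the setting with all detected probes held, 183 were called with ST045849 at 12 hours (105 higher, 78 lower) and 583 at 24 hours (304 higher, 279 lower). Between scrambled and vehicle limma called 0 and 1 of these probes. Of the named probes 8.57% were called at 12 hours and 21.4% at 24 hours, against 4.56% and 14.5% of those without a name. Groups of 3 arrays were not tested for single arrays that stand apart.

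ATF4 list genes rose and G1/S genes fell with ST045849, and the difference from the siOGT effect passed the test at 12 hours for both lists, with the G1/S difference at 24 hours lost with an estimated correlation (adjusted p = 0.0856). The tables argue against a failed knockdown, since the group means left at most 36.1% of the OGT transcript over 2 probes and 2 times; single arrays varied, with the smallest OGT fall in replicate 2 of 24 hours (-0.79), but where it changed by -2.50 to -2.20 the ATF4 median with siOGT was still 0.09 to 0.12. They argue against a rise of the list as a whole hidden by the scrambled control, since the ATF4 median between siOGT and vehicle was at most 0.12, against 1.05 and 1.19 with ST045849. Of single members, STC2 was called higher with siOGT than with vehicle at 24 hours (0.62, limma adjusted p = 0.0165). They argue against background correction or quantile normalization as the cause, since the list medians under the other settings were at least 0.757 of those reported. Effects of the compound other than on OGT, and OGT protein or activity that outlasts its transcript, were not tested and may each account for the difference.

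Beside OGT, 12 genes were called between siOGT and scrambled at 24 hours, and 11 of them had the same direction at 12 hours. The dim scrambled array, replicate 1, does not account for the size of their median change, since without it that median was 0.947 of that with it. The genes were picked with that array included, and without it the count of calls in the comparison fell to 2. That 12 of 12 kept their direction is no support. In all 13 called genes the siOGT arrays lay on 1 side of the scrambled arrays, so no direction could change. Whether the scrambled arrays rather than the siOGT arrays stand apart cannot be told apart for the 12 genes as a set: scrambled minus vehicle at 12 hours, signed by the call, had a median of -0.051, with 7 of 12 opposite, and siOGT minus vehicle had 0.24, as large as siOGT minus scrambled (0.22). For LMLN alone scrambled lay below vehicle by -0.42 ± 0.14 at 12 hours (SE; limma unadjusted p = 0.00591, adjusted p = 1). LMLN with siOGT lay above vehicle by 0.24 at 12 hours and 0.29 at 24 hours (limma adjusted p = 0.772 and 0.478). A scrambled control that stands apart for LMLN is thus a hypothesis. A smaller siOGT difference from vehicle, in the other direction, is not excluded.

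On the first component of all 24 arrays, those of 12 hours replicate 3 and 24 hours replicates 1 and 3 did not overlap with the others in any treatment. Of the 10 ways to call 3 of the 6 times and numbers 24 hours in all treatments alike, this one gave 290 genes over time in the ST045849 arrays, 146 in siOGT and 79 in scrambled, none of which are needed to find the sets, against at most 0, 0 and 1 for the other 9, the labelled one among them, although on a first component of its own 6 arrays scrambled did not divide this way. This is consistent with exchanged time labels of 12 hours replicate 3 and 24 hours replicate 2, and as well with a batch or culture difference that the labels do not name, and nothing in the sources used here separates these. Dimmer arrays do not account for it, since the percent of probes detected differed by -0.192 to 1.51 between the sets, in both directions. OGA, lower with siOGT at each time, followed the same sets: its largest gap was 0.785 of its range, so the correlation with OGT that had been written down beforehand was not used, and vehicle and scrambled arrays showed at most 0.170 of its set difference (-0.23 and -0.02 against -1.32). With 1 array left out the OGA change ranged from -1.03 to -0.32 at 12 hours and from -1.58 to -0.88 at 24 hours, and whether cells with less OGT may hold less OGA transcript stays open.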

How the results depend on the processing

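Vehicle as the control of siOGT, the mean siOGT effect over both times and the 4 settings with array sets were chosen only after the result was seen; the other alternatives were planned. A block for slides was not run, since the slides are not given in the sources used here, and the causes of the changes below were not tested, except that a fold threshold lowers a count by construction. Of 172 counts of called genes under alternatives 131 stayed within 1.5 times, as did 74 of 96 with 1 array left out. Both totals include counts of 0 that stayed 0. The totals below for named genes and lists likewise include those without a call that stayed without one. They do not measure how firm the calls are. Of 19140 values of named genes 17985 kept their direction and side of the threshold, 489 lost and 322 gained a call, 343 without a call moved, and 1 reversed: ARFIP2 between siOGT and control at 24 hours, 0.0080 with vehicle as the control (adjusted p = 0.995). With 1 array left out 10030 of 10692 were kept. Of 764 list tests 659 were kept, 26 lost and 61 gained a call. With the authors' processed values 1071 of the 1139 and 2402 of the 2516 genes called with ST045849 were called again. With median scaling 469 and 1462 were, and 2515 of the 2516 had the same sign. Signal over background limits dim genes, whose folds the text gives as bounds. Scrambled against vehicle at 24 hours gave 18 genes without background correction, 18 with the authors' values, 4 without a detection filter, 16 among probes detected on all 24 arrays, 16 with the replicate block, 5 with array weights, 2 with median scaling and 0 in a fit of the compared groups. The ST045849 effect minus the siOGT effect at 12 hours gave 336 without background correction, 336 with the authors' values, 57 with median scaling and 118 in a fit of the compared groups. ST045849 at 12 hours gave 472 with median scaling, 452 in a fit of the compared groups and 431 with a fold of at least 1.5, and ST045849 at 24 hours 971 with that fold. The siOGT comparison at 24 hours gave 2 with median scaling, 6 with a fold of at least 1.5 and 0 in a fit of the compared groups, and that at 12 hours 2 with all detected probes and 0 in a fit of the compared groups. The mean siOGT effect over both times gave 20. With the replicate block the change over time gave 1 gene in vehicle and 2 in scrambled. The replicates were treated as sharing only a number, since the labels do not say whether arrays of 1 number were run together: residuals of arrays with the same number were not correlated above 0.1 throughout in any comparison, and at 24 hours of siOGT 6 of 6 arrays correlated best with their own number. For siOGT against scrambled the highest values were 0.27 for replicate 3 at 12 hours and 0.24 for replicate 2 at 24 hours. For scrambled against vehicle the same replicates gave 0.24 and 0.24, and for ST045849 against vehicle -0.05 and -0.07. In each group these are the arrays of the other array set, so number and set cannot be told apart there. With the array set as a block scrambled against vehicle at 24 hours gave 5. With the set's own effect of each treatment as well, ST045849 at 12 hours gave 1765, siOGT 6 at 12 and 8 at 24 hours, and the difference of the effects at 12 hours 772, with an OGT change with ST045849 of 0.50 and 0.48 (adjusted p = 0.00984 and 0.0108). With the time taken from the array set siOGT at 24 hours gave 124, scrambled against vehicle at 12 hours 1, the change of the ST045849 effect over time 350, that of the siOGT effect 2, vehicle over time 165 and scrambled 79, with an OGT change with ST045849 of 0.41 and 0.57 (adjusted p = 0.0296 and 0.000847). With only the arrays whose set goes with their time, ST045849 at 12 hours gave 285, scrambled against vehicle at 24 hours 1, the change of the ST045849 effect over time 144, the difference of the effects at 12 hours 62 and scrambled over time 6, with an OGT change with ST045849 at 24 hours of 0.58 (adjusted p = 0.0141). The OGT change with ST045849 at 24 hours was 0.44 without background correction (adjusted p = 0.0247), 0.44 with the authors' values (adjusted p = 0.0248) and 0.50 in a fit of the compared groups (adjusted p = 0.0174). With siOGT it was -1.70 and -1.83 in that fit. Camera with an estimated correlation called 3, 3 and 0 lists for ST045849 at 12 and 24 hours and siOGT at 12 hours. Fry called 0 and 1 for siOGT at 12 and 24 hours, and 20, 22 and 6 for ST045849 at 12 and 24 hours and siOGT at 24 hours when members could move either way. With the array set and its own effect of each treatment, an estimated correlation called 7 lists for ST045849 at each time, and for siOGT at 24 hours the preset one called 2, against 3 with the set as a block. For siOGT at 24 hours 1 list was called without background correction, 1 with the authors' values and 2 with the replicate block. The calls shared by ST045849 and siOGT at 24 hours were 1 lower without background correction, 1 lower with the authors' values, 0 higher with median scaling and 2 higher with the replicate block. With each array left out, ST045849 at 12 hours gave 486 to 1052 genes (486 without its replicate 3, 498 without vehicle replicate 3) and at 24 hours 1705 to 2414. For siOGT it gave 0 to 1 (0 without siOGT replicate 3) at 12 hours and 2 to 30 at 24 hours (2, 30 and 2 without siOGT replicates 1, 2 and 3, and 2, 3 and 25 without those of scrambled). Scrambled against vehicle at 24 hours gave 1 to 45 (1, 1 and 2 without vehicle replicates 1, 2 and 3, 2 and 45 without scrambled replicates 1 and 3). The difference of the effects at 12 hours gave 98 to 256 (98 without ST045849 replicate 3, 113 without vehicle replicate 3, 123 and 121 without scrambled replicates 1 and 2, 133 without siOGT replicate 3) and at 24 hours 1062 to 1746 (1062 without scrambled replicate 2). Scrambled over time gave 0 to 1 (1 without replicate 3 of either time). The OGT change with siOGT was -1.88 to -1.46 at 12 hours (-1.46 without siOGT replicate 3, adjusted p = 0.0595) and -2.21 to -1.60 at 24 hours, and with ST045849 0.37 to 0.57 and 0.43 to 0.56.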

Other observations

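The permutation tests over both times, siOGT against vehicle, the mean siOGT effect, and the splits of lists with an estimated correlation were chosen only after the result was seen. With ST045849, single genes changed in lists that did not shift as a whole at 12 or 24 hours. Of 23 p53 target genes 5 rose and 1 fell at 12 hours and 5 rose and 3 fell at 24 hours (camera adjusted p = 0.475 and 0.526). GDF15, a stress-induced cytokine (1.63 ± 0.22 at 24 hours, SE, n = 3 arrays per group), and SESN2, an inhibitor of mTORC1 (1.34 ± 0.25), were among them and are also in the ATF4 list. Of 16 immediate early genes 3 rose at 12 hours and 6 rose and 1 fell at 24 hours (adjusted p = 0.0907 and 0.0895), among them the transcription factor genes ATF3 (1.38 ± 0.20 at 24 hours, also in the ATF4 list) and JUN (0.77 ± 0.12). Of 24 interferon response genes 2 rose at 12 hours and 7 rose and 2 fell at 24 hours (adjusted p = 0.384 and 0.329), among them the exonuclease gene ISG20 (1.11 ± 0.21) and IFI35 (0.85 ± 0.15), and median scaling turned the list's median at 24 hours from 0.17 to -0.01, that of the p53 list from 0.15 to -0.04 and that of the apoptosis list from 0.09 to -0.09. Of 21 fatty acid genes 1 rose and 4 fell at 12 hours and 2 rose and 7 fell at 24 hours (adjusted p = 0.198 and 0.138), among them the elongase genes ELOVL7 (-1.26 ± 0.24) and ELOVL6 (-0.77 ± 0.15) and the synthase gene FASN (-0.46 ± 0.13). Of 22 glycolysis genes 2 fell at 12 hours and 1 rose and 4 fell at 24 hours (adjusted p = 0.223 and 0.103), among them LDHA, of lactate formation (-0.46 ± 0.09). Of 23 apoptosis regulators 2 rose at 12 hours, and 2 rose and 1 fell at 24 hours (adjusted p = 0.223 and 0.667), among them PMAIP1, a BH3-only protein gene (0.65 ± 0.18).

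Of 13 genes of O-GlcNAc cycling and the hexosamine pathway 1 rose at 12 hours and 2 at 24 hours of ST045849 (camera adjusted p = 0.499 and 0.563). These were GFPT1, the enzyme of the first step of the hexosamine pathway (0.72 ± 0.17 and 0.80 ± 0.17), and at 24 hours GNPDA1 (0.41 ± 0.10), while median scaling turned the list's median at 24 hours from 0.13 to -0.09. Of 9 metallothionein and metal transport genes 1 rose at 12 hours, and 2 rose and 1 fell at 24 hours (adjusted p = 0.329 and 0.564), among them MT1E (0.95 ± 0.30), whose probe was not separated from other MT1 genes of similar sequence. Of 7 NF-kB genes 0 were called by limma at 12 hours and 2 fell at 24 hours (adjusted p = 0.603 and 0.433), among them NFKBIA (-0.34 ± 0.10). Of 48 respiratory chain genes 1 fell at 12 hours, and 1 rose and 2 fell at 24 hours (adjusted p = 0.603 and 0.96), among them NDUFA6 (-0.55 ± 0.11). Of 29 proteasome genes 0 were called by limma at 12 hours and 3 fell at 24 hours (adjusted p = 0.0528 and 0.0655), and of 45 ribosomal protein genes 0 were called at 12 hours, and 3 rose and 1 fell at 24 hours (adjusted p = 0.603 and 0.575). Of 22 heat shock genes 1 rose and 2 fell at 12 hours (adjusted p = 0.0651), and of 17 glucose-responsive and hypoxia genes 3 rose (adjusted p = 0.0661). Of 18 luminal markers 2 rose and 3 fell at 12 hours, and 1 rose and 3 fell at 24 hours (adjusted p = 0.847 and 0.635). Lists too short for a test were the aryl hydrocarbon receptor genes, of which 1 and 3 of 4 rose, the neuroendocrine markers, of which 0 and 1 of 2 rose (TUBB3, a neuronal tubulin, 0.72 ± 0.20), and the basal and stromal markers, of which limma called 0 of 3 at either time. The stromal markers VIM and ACTA2 differed by 0.02 (adjusted p = 0.937) and -0.64 (adjusted p = 0.199) at 24 hours.

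The mean siOGT effect over both times called 5 higher and 15 lower genes, among them EEF2K, the kinase of elongation factor 2 (-0.46 ± 0.07, limma adjusted p = 0.0105), PHLPP2, a phosphatase of AKT (-0.41 ± 0.07, adjusted p = 0.0201), MAP2K4, a stress-activated kinase (-0.68 ± 0.13, adjusted p = 0.0268), and SOX4, a transcription factor gene (-0.43 ± 0.09, adjusted p = 0.0443). The smallest p was that of LMLN (1.04 ± 0.10, limma adjusted p = 3.77e-06), for which the scrambled control may stand apart. Against vehicle, siOGT called OGT alone at 12 hours, and 6 higher and 3 lower genes at 24 hours, among them ZFR (-0.54, adjusted p = 0.0165) and STC2, of the ATF4 list (0.62, adjusted p = 0.0165). EEF2K, PHLPP2, MAP2K4 and SOX4 were not called against vehicle at either time. In exact permutation tests stratified by time, OGT lay 1.40-fold and OGA 1.54-fold above vehicle with ST045849, and with siOGT OGT changed by -1.77 and OGA by -0.96 on the log2 scale. Each had 6 of 6 treated arrays beyond the controls of the same time and p = 0.005, the smallest that 400 permutations can give (adjusted p = 0.005 over 4 tests).

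Between vehicle at 24 and 12 hours the G2/M list rose (median 0.14, adjusted p = 0.00642; adjusted p = 0.977 with an estimated correlation). Between scrambled at 24 and 12 hours the heat shock, NRF2 and metallothionein lists were lower, by medians of -0.11, -0.11 and -0.35 (adjusted p = 0.0262, 0.0419 and 0.0262; adjusted p = 0.977 for each with an estimated correlation). The times differ in how many arrays of each array set they hold, and with the sets in the model the G2/M median in vehicle was -0.04.

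Other splits of the same arrays were counted for each number of calls. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. ST045849 gave 1139 genes at 12 hours and 2516 at 24 hours, each with 0 as the highest of the other splits, siOGT 1 and 13 genes with 4 and 2 as the highest, and scrambled against vehicle 0 and 9 with 0 as the highest for each. As many genes came from 1 split in 4 of these 6 comparisons, from 3 splits for siOGT at 12 hours and from 10 for scrambled against vehicle at 12 hours. The change over time gave 0 genes in vehicle and in scrambled, with 0 and 1 as the highest, and 10 of 10 splits gave as many. With the preset correlation ST045849 gave 9 and 11 lists, with 9 as the highest of the other splits for each (2 and 1 splits gave as many), and siOGT gave 1 and 0, with 7 as the highest (8 and 10 splits). Lists of correlated genes were thus called in other splits as well, which keep part of the effect. With an estimated correlation ST045849 gave 3 and 3 lists with 0 as the highest (1 split for each), and siOGT 0 and 0 with 1 and 0 as the highest (10 splits for each). For the mean siOGT effect, a comparison added after the result was seen, only the labelled split gave as many genes (20 genes, highest other 3, 1 of 100 splits). This argues against chance for the count as a whole, which includes OGT, and does not test any other single gene. For the difference of the effects at 12 hours (207 genes, highest other 432, 7 of 100) and at 24 hours (1662 genes, highest other 951, 1 of 100) the splits do not test chance. The 89 that mixed ST045849 with vehicle arrays gave at most 49 and 3 genes through the loss of the ST045849 effect itself, and the 10 others, of which 6 and 0 gave as many, are too few. For the effects at 24 minus 12 hours, 0 genes for ST045849 and for siOGT stood against 2073 and 23 as the highest, with 100 of 100 splits as large, and the splits with many genes point to a structure of the samples, the treatment itself, which those splits shift between the times.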
